A study of Arabidopsis thaliana with 24 samples.

How the data were processed

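The series holds 24 RNA-seq libraries from rosettes of Arabidopsis thaliana Col-0, 3 biological replicates in each of 8 groups. Per the labels' protocols, plants grown on soil were moved to fresh soil at 2 weeks, treated 14 days later, and sampled 16 h after watering with 150 mM NaCl, 200 mM mannitol or the mixture. No such watering was recorded for the control and heat groups. In comparisons with control or with heat alone, watering itself therefore cannot be told apart from salt or mannitol. Watering also enters both the salt and the mannitol effect, while their combination was watered a single time. Departures from a sum that holds both effects thus cannot be told apart from a watering effect. Heated plants spent the last 4 h in another cabinet at 35 °C, while the rest stayed at 22 °C. The labels' protocols give a poly(A)-based kit and paired reads of 100 bp, with 12 libraries per lane, but not which library shared a lane. They do not say whether a replicate was 1 plant or a pool, so p-values measure the spread between these samples.

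Per the submitters' processing notes, the tools were CASAVA (version not given in the sources used here), kallisto 0.45.1 and sleuth 0.30.0. Per the file headers, counts came from kallisto and q-values from sleuth. The deposited table holds 27655 genes with 1 transcript model each. Its deposited estimated counts are, per the file headers, raw kallisto counts, yet in every library values are multiples of a constant between 0.797 and 1.25 (94.7% to 95.2% of values). That constant was divided out before the estimated counts were rounded and tested, so totals are counts of reads. The deposited TPM values (a signal, transcripts per M) sum to 0.920 to 1.12 M per library, so they had been rescaled before deposit, and serve here for levels only. The authors' q-values (a p-value corrected by sleuth) served only for the comparison with the calls made here. The deposited fold changes were estimated by the authors in sleuth, per the file headers, and their size against the TPM shows the natural log (ln). The table names no genome build, so no coordinates are printed. Symbols come from a reference gene table matched on the gene identifier (27445 genes), because 22 names in the deposited column had turned into dates.

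Totals ran, in M (mega) reads, from 12.5 to 19.5 M per library, with group means from 13.8 to 18.4 M. Each library detected 21885 to 22379 genes, and its 10 most abundant genes held 7.06% to 11.4% of reads. Replicates differed by more than counting noise (chi-square per degree of freedom 3.31 to 25.0), so none is a copy of another, and their log2 values correlated at 0.989 to 0.996.

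Counts of all 24 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and robust quasi-likelihood F tests. This left 20027 genes. Each treatment was compared with control, each combination with the sum of its single effects on the log2 scale, and 4 combinations with the stress they share. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, separately per comparison. The SE is that of the log2 fold change in the fit. Groups, tests and a first set of alternatives were fixed before the data were examined. Others were chosen after seeing the data: deposited counts without dividing out the constant, limma 3.58.1 with trend on log2(TPM + 1), library totals alone, 4 libraries with high organelle shares left out, and other definitions of unknown function. The first set was DESeq2 1.42.0, RLE scaling, no filter on low genes, a log2 fold change of at least 1, the groups of the comparison only, the replicate block and leaving out each library in turn.

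TMM takes the bulk of genes as unchanged. With library totals alone, the median log2 fold change over all genes was 0.11 for salt, 0.11 for salt plus mannitol, 0.12 for mannitol plus heat and 0.17 for all 3 stresses, so shares of rises and falls are given under each scaling. Which scaling is nearer the amount of RNA per cell cannot be told without spike-ins.

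Named genes are the largest rises and falls with an adjusted p under 0.05 and a mean TPM of at least 5 in a compared group. Against control only, every treated library also had to lie beyond every control. Up to 6 of these changes per direction were taken against control and 5 elsewhere. Up to 4 called members of each fixed list were added. Genes without reference counts get a lower bound of the fold, with 3 counts put in for the reference group, and genes with 1 to 3 reference counts get a ratio of counts with a 95% interval that covers counting error only. Not every gene that met the rule is printed: those whose call was lost when a library was left out are mostly omitted, as are a few values that equal a number used as a setting.

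The gene lists were written before testing: small heat shock proteins, large chaperones, heat shock factors and regulators, ABA synthesis, signalling and breakdown, dehydration- and ABA-responsive genes, osmolyte metabolism, sodium and potassium transport, photosynthesis, salicylic acid and immunity, jasmonate, reactive oxygen, the unfolded protein response, expansins and xyloglucan endotransglucosylases, aquaporins, the circadian clock, senescence, cytosolic ribosomal proteins (244 members), and markers of root (4 of 7 measured), inflorescence (1 of 9) and seed or pollen (0 of 6). Lists were tested against all other genes with camera at a preset correlation of 0.01 and with an estimated correlation, and by fry, which asks by rotated residuals whether the list's genes move, on balance, in a single direction; no statement here rests on fry. Of 126 tests of a list in a treatment, 68 were called with the preset and 4 also with the estimated correlation. Camera p-values with the preset are therefore ranks more than error rates.

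Unknown function means a class of not assigned unknown or no entry in the deposited annotation (7485 genes in the table). Shares were compared by two-sided Fisher exact tests. In counts simulated from the fit, edgeR recovered genes changed between salt and control at 56.7, 79.1 and 90.9% for folds of 1.5, 2 and 4. It made 5 false calls (3.21%), and camera called 0 of 20 unchanged lists. The simulated genes were drawn independently, so these lists do not test camera where genes vary together. Replicate numbers recur in all groups. Residuals of the same number correlated at a mean of 0.00881 against -0.00445 for other numbers, with 14 of 24 libraries closest to their own number, where 8 would follow from chance. For mannitol plus heat against heat, all 3 same-number correlations were above 0.1, as were 25% of all same-number pairs. There the numbers may pair the samples, by the data and not by the labels. In no other comparison did all 3 pass. The labels do not say what a number marks, so pairing is left open throughout. The fit has no block.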

Results

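Rosettes of Arabidopsis thaliana Col-0 were compared across control, salt, mannitol, heat and their 4 combinations, with 3 libraries per group. Changes are log2 fold changes ± SE from n = 3 libraries per group unless another n is given, and levels are mean TPM ± SD. For gene lists, counts in brackets are those adjusted over the list alone, and where a list is given with its uncalled genes and no such bracket these counts were the same. A gene is said to rise or fall only where its adjusted p lies under 0.05. Heat separated the libraries most: the leading component held 59.8% of the variance, with all 12 unheated libraries on its negative side and all 12 heated libraries on its positive side. The next component held 12.9%. Every gene given below as a largest change against control had all 3 treated libraries beyond all 3 controls. This was not required for departures from the sum or for comparisons of stressed groups with each other. Where leaving out 1 library moved the fold of a printed gene by more than 1.5 times, the value without that library is given. Control 1 stood apart for several defence and jasmonate genes: PR1 was at TPM 655 against 214 and 102 in the other controls, VSP1 at 129 against 61.4 and 27.2, PDF1.3 at 402 against 95.9 and 25.1 and AIG1 at 21.7 against 6.32 and 3.07.

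**Figure D1:**
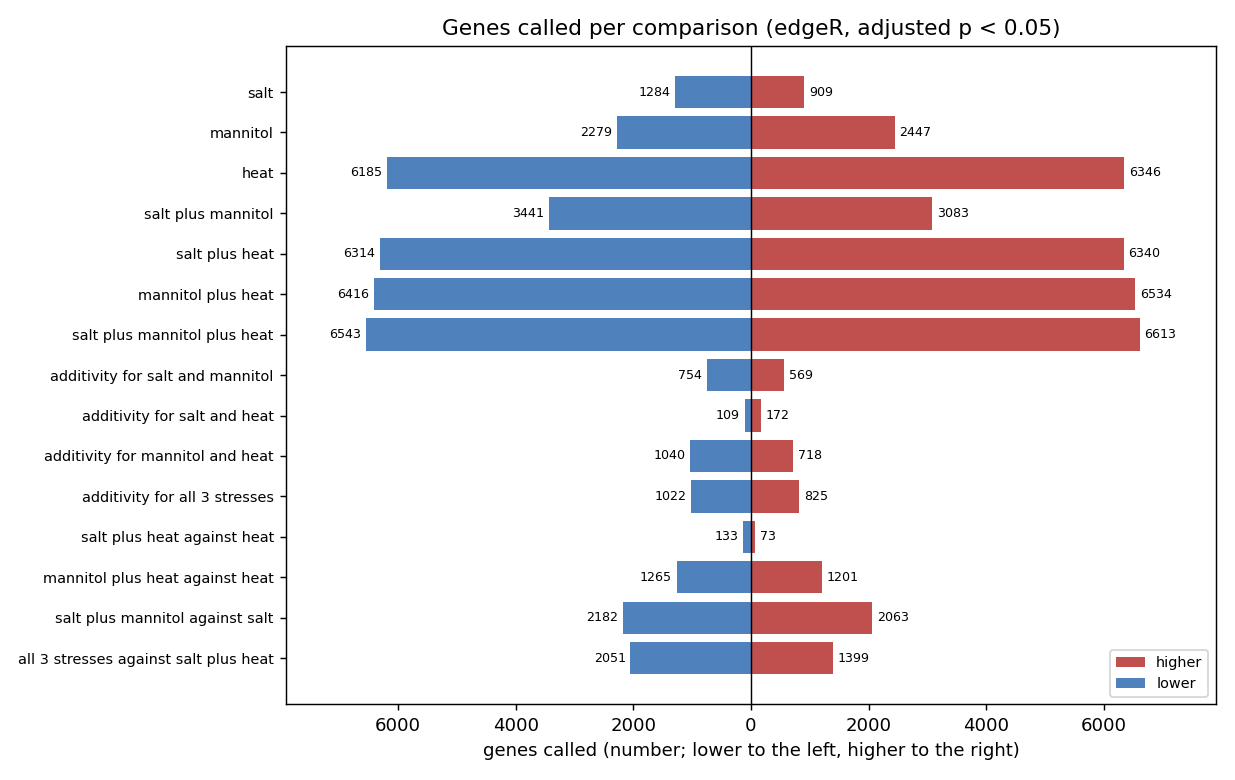
Genes higher and lower in each comparison, from edgeR quasi-likelihood tests with 3 libraries per group.

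Salt at 22 °C raised genes of dehydration and abscisic acid (ABA) response. LTP4, a lipid transfer protein, rose by log2 5.77 ± 0.87 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000705, TPM 419 ± 158 against 7.41 ± 3.99, n = 3 per group). AT3G02480, of the late embryogenesis abundant family, rose by 5.23 ± 0.96, RD29B by 4.91 ± 0.91, the membrane protein TSPO by 4.88 ± 0.90 and DAA1 by 4.42 ± 0.71. LEA7 rose by 6.47, a call lost with 1 library left out (6.18 and adjusted p = 0.0542 without control 3). The largest falls with a stable call were the protease inhibitor gene AT1G73325 (-2.60 ± 0.48), the thionins THI2.2 (-2.08 ± 0.19, TPM 24.6 ± 3.70 against 103 ± 28.2) and AT1G66100 (-2.04 ± 0.25), and MEE3 (-2.03 ± 0.29).

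Of 27 measured dehydration- and ABA-responsive genes, 16 rose, 1 fell and 10 were not called (20 and 1 adjusted over the list alone), with a median of 0.89. Camera ranked it at adjusted p = 1.74e-15 (adjusted p = 0.311 with an estimated correlation). Salt lowered jasmonate genes: of 21 measured, 0 rose, 11 fell and 10 were not called (0 and 14 adjusted over the list alone), among them the lipoxygenase LOX2 (-1.15 ± 0.20) and JAZ5 (-1.11 ± 0.23). The camera test gave adjusted p = 7.09e-12 (adjusted p = 0.154 with an estimated correlation). In the photosynthesis list of 39 genes, 0 rose, 17 fell and 22 were not called (0 and 26 adjusted over the list alone). Tested by camera, it had adjusted p = 7.63e-10 (adjusted p = 0.439 with an estimated correlation). RBCS1A, a small subunit gene of Rubisco whose reads can be shared with its paralogs, fell by 0.78 ± 0.12 (TPM 14257 ± 589.9 against 24194 ± 1562). Among 17 large chaperones and co-chaperones, 7 rose, 1 fell and 9 were not called (9 and 1 adjusted over the list alone), with rises of HSP70 (2.05 ± 0.28), FKBP65 (1.35 ± 0.14) and HOP3 (0.90 ± 0.18). The list stood at camera adjusted p = 1.14e-07 (adjusted p = 0.154 with an estimated correlation). The small heat shock proteins showed no call (13 measured). Of 15 heat shock factors and regulators, 3 rose, 1 fell and 11 were not called, including HSFA2 (1.42 ± 0.28) and MBF1C (0.76 ± 0.15). Camera returned adjusted p = 0.00515 (adjusted p = 0.355 with an estimated correlation).

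Among 17 osmolyte genes, 4 rose, 3 fell and 10 were not called (5 and 4 adjusted over the list alone), with GOLS2 of raffinose synthesis up (1.09 ± 0.24) and GOLS3 down (-0.86 ± 0.17); the list's median was -0.03, its mean 0.01 and its camera direction up (camera adjusted p = 0.712). For 21 genes of ABA synthesis, signalling and breakdown, 4 rose, 1 fell and 16 were not called (9 and 3 adjusted over the list alone). In sodium and potassium transport (17 genes), 1 rose, 1 fell and 15 were not called, the fall being KAT1 (-0.52 ± 0.11). Aquaporins (16) gave 2 falls, including PIP2A (-0.39 ± 0.08), and the clock list (15) 1 rise and 2 falls, with PRR5 at -0.93 ± 0.14. The cell wall gene XTH22 rose by 2.44 ± 0.53, the only call among 13 expansins and xyloglucan endotransglucosylases. Smaller lists gave 1 rise of 15 for the unfolded protein response, 1 of 15 for senescence, 1 fall of 24 for salicylic acid (1 rise and 0 falls with library totals alone) and 1 fall of 4 root markers. For reactive oxygen genes (19), 1 rose, 3 fell and 15 were not called, but 3 rose and 1 fell with library totals alone, with FSD1 up by 0.48 ± 0.10. For cytosolic ribosomal proteins (223), 3 rose, 12 fell and 208 were not called, but 9 rose and 3 fell with library totals alone, so no direction is given for these lists.

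With salt, 2193 genes passed the test, 909 higher and 1284 lower, and 283 differed at least 2-fold. Leaving out 1 library gave 1400 without control 2, 1043 without control 3, 1414 without salt 1, 1300 without salt 2 and 1276 without salt 3. With TMM factors 41.5% of the calls were higher, and with library totals alone 76.5% of 3181 calls, so the balance of rises and falls depends on the scaling. Without control 1, AT3G02480 stood at log2 5.90, TSPO at 5.51 and DAA1 at 5.23. Without control 2, RD29B stood at log2 5.79.

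Mannitol at 22 °C raised GSTF3, a glutathione S-transferase gene, by log2 6.02 ± 0.48 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.28e-07, TPM 47.1 ± 16.0 against 0.722 ± 0.0947, n = 3 per group). The receptor-like kinase gene CRK20 rose by 5.40 ± 0.31, LTP4 by 5.04 ± 0.86, the methyltransferase gene PXMT1 by 5.01 ± 0.51 (TPM 322 ± 109.6 against 9.96 ± 3.41) and RD29B by 4.83 ± 0.90. PCC1, a gene under pathogen and clock control, fell by 3.40 ± 0.36 (TPM 311 ± 119 against 3139.6 ± 797). Further falls were AT2G14247 (-4.44 ± 0.62), the defensin-like AT1G13609 (-4.29 ± 0.95), the vegetative storage protein VSP1 (-3.57 ± 0.63) and AIG1 (-3.36 ± 0.55). Mannitol 3 stood apart for dehydration genes, with LTP4 at TPM 579 against 42.5 and 117 in the other replicates.

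Of 27 dehydration- and ABA-responsive genes, 17 rose, 1 fell and 9 were not called. Without mannitol 3, LEA7 (edgeR quasi-likelihood adjusted p = 0.0999), TSPO (0.0699) and the ABA gene HAI2 (0.214) were no longer called. Members called were not recounted without this library, for the dehydration- and ABA-responsive list or any other. For the dehydration- and ABA-responsive list camera gave adjusted p = 5.44e-08 (adjusted p = 0.439 with an estimated correlation). Of 21 ABA synthesis, signalling and breakdown genes, 9 rose, 2 fell and 10 were not called (10 and 3 adjusted over the list alone), with the synthesis gene NCED3 (1.65 ± 0.29) and the breakdown gene CYP707A3 (1.29 ± 0.28) up. Its camera result was adjusted p = 0.0144 (adjusted p = 0.611 with an estimated correlation). The salicylic acid and immune list of 24 was mixed: 6 rose, 9 fell and 9 were not called (7 and 11 adjusted over the list alone), the falls including PR1 (-2.89 ± 0.70), WRKY38 (-2.32 ± 0.29) and WRKY54 (-2.25 ± 0.19). Camera put it at adjusted p = 0.0409 (adjusted p = 0.654 with an estimated correlation). Jasmonate genes (21) went down: 0 rose, 13 fell and 8 were not called (0 and 14 adjusted over the list alone), with THI2.1 (-3.19 ± 0.67) and JAZ7 (-2.25 ± 0.48) beside VSP1. The camera test gave adjusted p = 1.14e-07 (adjusted p = 0.311 with an estimated correlation). For photosynthesis (39 genes), 0 rose, 28 fell and 11 were not called (0 and 31 adjusted over the list alone), with LHCA1 at -0.58 ± 0.09 and RBCS1A at -0.59 ± 0.12. Tested by camera, it had adjusted p = 4.67e-10 (adjusted p = 0.439 with an estimated correlation). For cytosolic ribosomal proteins (223 measured), 67 rose, 2 fell and 154 were not called (81 and 2 adjusted over the list alone), with AT5G15750 (0.95 ± 0.13) and AT3G58660 (0.94 ± 0.12) up. The list stood at camera adjusted p = 2.30e-12 (adjusted p = 0.503 with an estimated correlation).

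Of 17 large chaperones, 9 rose, 0 fell and 8 were not called, led by HSP70 (1.79 ± 0.28), HSP60 (0.70 ± 0.10) and HSP90.5 (0.68 ± 0.11). This list reached camera adjusted p = 0.000115 (adjusted p = 0.311 with an estimated correlation). Of 15 unfolded protein response genes, 7 rose, 0 fell and 8 were not called (8 and 0 adjusted over the list alone), with BZIP60 (0.82 ± 0.13) and BZIP17 (0.49 ± 0.10). The camera value was adjusted p = 0.000469 (adjusted p = 0.475 with an estimated correlation). In the clock list of 15, 9 rose, 0 fell and 6 were not called, including PRR5 (0.82 ± 0.12), RVE1 (0.74 ± 0.15) and GRP7 (0.55 ± 0.09). Against all other genes, camera gave adjusted p = 0.00163 (adjusted p = 0.311 with an estimated correlation). Aquaporins (16) fell: 0 rose, 6 fell and 10 were not called, with PIP2;7 (-0.77 ± 0.14) and PIP2A (-0.48 ± 0.08). Camera ranked it at adjusted p = 0.000776 (adjusted p = 0.439 with an estimated correlation). Osmolyte genes (17) were mixed, 7 rose, 3 fell and 7 were not called, with ERD5, a proline dehydrogenase gene, down (-1.37 ± 0.25). The counts of rises and falls were 1 and 4 for expansins and xyloglucan endotransglucosylases (13), 3 and 3 for sodium and potassium transport (17), 4 and 1 for reactive oxygen (19), 3 and 2 for heat shock factors (15), 2 and 1 for senescence (15) and 0 and 2 for root markers (4). Of 13 small heat shock proteins 1 fell, and 1 rose and 0 fell with library totals alone.

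With mannitol, 4726 genes passed the test, 2447 higher and 2279 lower, and 814 differed at least 2-fold. Leaving out 1 library gave between 3239 (without mannitol 3) and 4967 (without mannitol 1). With TMM factors 51.8% of the calls were higher, and with library totals alone 73.2% of 5225 calls. Without mannitol 3, LTP4 stood at log2 3.35, RD29B at 3.38 and THI2.1 at -7.29. Without control 2, RD29B stood at log2 5.69. Without mannitol 1, AT1G13609 stood at log2 -4.91. Without control 1, VSP1 stood at log2 -2.87, AIG1 at -2.23 and PR1 at -1.88.

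Heat at 35 °C for 4 h raised transcripts that were absent or nearly absent in control rosettes. AT4G19430, of unknown function, had no control count and rose at least 411-fold, and AT5G38650, annotated as a proteasome maturation factor, at least 185-fold. Reads of AT5G38650 can be shared with another transcript, which was not tested. Among genes with control counts, the small heat shock proteins HSP22.0 (9.65 ± 0.75), HSP21 (9.26 ± 0.85) and HSP23.6 (9.17 ± 0.26) led (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p for HSP23.6 = 6.40e-17, n = 3 per group), beside the DnaJ-domain gene AT1G71000 (9.17 ± 0.40). APX2, an ascorbate peroxidase gene with 2 control counts, gave a count ratio of 645 (178 to 5335). PCC1 fell by 5.63 ± 0.42 (TPM 63.6 ± 19.1 against 3139.6 ± 797), the morning clock gene LHY (-4.66 ± 0.22), PCR1 (-4.66 ± 0.69), the chlorophyll synthesis gene PORA (-4.44 ± 0.25), AIG1 (-4.20 ± 0.61) and AT1G22690 (-4.02 ± 0.40).

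Of 13 small heat shock proteins, whose reads can be shared within the HSP17 subfamily, 12 rose, 0 fell and 1 was not called, with a median of 8.37. Camera returned adjusted p = 9.91e-13 (adjusted p = 0.0859 with an estimated correlation). Of 17 large chaperones, 16 rose, 0 fell and 1 was not called, led by HOP3 (7.75 ± 0.16), HSP70 (7.69 ± 0.33), FKBP65 (7.07 ± 0.15) and HSP90.1 (6.99 ± 0.21). Its camera result was adjusted p = 4.86e-15 (adjusted p = 0.0318 with an estimated correlation). Of 15 heat shock factors and regulators, 10 rose, 1 fell and 4 were not called, with HSFA2 (6.74 ± 0.21), MBF1C (5.34 ± 0.16), DREB2A (4.71 ± 0.31) and HSFA3 (4.07 ± 0.40). The camera test gave adjusted p = 0.000180 (adjusted p = 0.280 with an estimated correlation). The unfolded protein response list (15) gave a near-complete rise: 14 rose, 1 fell and 0 were not called, with ERDJ3A (4.05 ± 0.17), BIP2 (2.47 ± 0.14) and BIP1 (2.27 ± 0.12) up and BIP3 down (-2.52 ± 0.39). Tested by camera, it had adjusted p = 1.37e-08 (adjusted p = 0.311 with an estimated correlation). Large chaperones were the only list whose camera call held with an estimated correlation, here and in the 3 combinations with heat.

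The salicylic acid and immune list (24) fell: 1 rose, 18 fell and 5 were not called, including WRKY54 (-2.94 ± 0.20), WRKY38 (-2.76 ± 0.31) and PR1 (-2.61 ± 0.69). The list stood at camera adjusted p = 1.92e-05 (adjusted p = 0.355 with an estimated correlation). In photosynthesis (39), 4 rose, 28 fell and 7 were not called, with LHCB2.3 (-2.59 ± 0.14), SBPASE (-1.08 ± 0.11) and RBCS1A (-1.15 ± 0.12). Camera returned adjusted p = 0.000162 (adjusted p = 0.644 with an estimated correlation). Clock genes (15) mostly rose apart from LHY: 11 rose, 2 fell and 2 were not called (11 and 3 adjusted over the list alone), with the RNA-binding protein gene GRP7 (3.55 ± 0.10, TPM 5884 ± 932 against 506 ± 40.6), LUX (3.09 ± 0.18) and BOA (3.88 ± 0.37). For this list camera gave adjusted p = 0.00515 (adjusted p = 0.342 with an estimated correlation). Aquaporins (16) rose: 12 rose, 1 fell and 3 were not called, led by PIP2;3 (3.47 ± 0.16), TIP1;1 (1.89 ± 0.12), PIP2B (1.56 ± 0.11) and TIP2;2 (1.52 ± 0.11). Camera put it at adjusted p = 0.000911 (adjusted p = 0.439 with an estimated correlation). Dehydration- and ABA-responsive genes (27) gave 10 rises and 0 falls, with LTP4 (7.38 ± 0.90), LTP3 (4.45 ± 0.49), a paralog that can share reads with LTP4, COR47 (1.98 ± 0.35) and ERD10 (1.49 ± 0.33). This list reached camera adjusted p = 0.0125 (adjusted p = 0.680 with an estimated correlation). In the osmolyte list (17), 5 rose, 8 fell and 4 were not called (6 and 9 adjusted over the list alone), with the proline synthesis gene P5CS1 down (-1.96 ± 0.20) and P5CR (2.08 ± 0.10) and GOLS1 (2.04 ± 0.13) up.

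In cytosolic ribosomal proteins (223), 85 rose, 29 fell and 109 were not called (83 and 28 adjusted over the list alone), with AT5G39850 (1.56 ± 0.13) and AT3G46210 (1.48 ± 0.11) up. For this list camera gave adjusted p = 0.0227 (adjusted p = 0.808 with an estimated correlation). Reactive oxygen genes (19) gave 9 rises and 3 falls, with ferritin FER1 up (2.46 ± 0.49, TPM 1022 ± 605 against 188 ± 38.5) and FSD1 up (1.41 ± 0.10). Rises and falls were 11 and 2 for ABA genes (21), with ABI1 up (1.27 ± 0.13) and ABA1 down (-1.21 ± 0.10), 2 and 6 for jasmonate (21), with LOX2 at -1.23 ± 0.20, 1 and 3 for expansins and xyloglucan endotransglucosylases (13), 5 and 3 for senescence (15), with ORE1 at 2.00 ± 0.20, and 0 and 2 for root markers (4). Sodium and potassium transport (17) gave 6 and 6, but 7 and 4 with library totals alone. FUL, the only measured inflorescence marker of 9, fell by log2 0.95 ± 0.41, a call lost in 4 of 6 fits with 1 library left out (-0.76 and adjusted p = 0.167 without control 1, -0.96 and adjusted p = 0.0821 without control 2, -0.55 and adjusted p = 0.238 without heat 1, and -0.96 and adjusted p = 0.0854 without heat 2). None of the 6 seed and pollen markers was measured.

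With heat, 12531 genes passed the test, 6346 higher and 6185 lower, and 3672 differed at least 2-fold. With TMM factors 50.6% of the calls were higher, and with library totals alone 56.4% of 12423 calls. Of 61 mitochondrial-encoded genes 60 were higher with a median of 3.91, a difference present in every heated group. All heated trays stood in another cabinet, so temperature and cabinet cannot be told apart. Without control 3, HSP21 stood at log2 10.25 and HSFA3 at 5.57. APX2, at log2 9.02 in the full fit, stood at 11.68 without control 3. Without control 1, PCR1 stood at log2 -3.61, AIG1 at -3.06, PR1 at -1.59 and BIP3 at -1.90. Without heat 2, FER1 stood at log2 1.87.

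**Figure D2:**
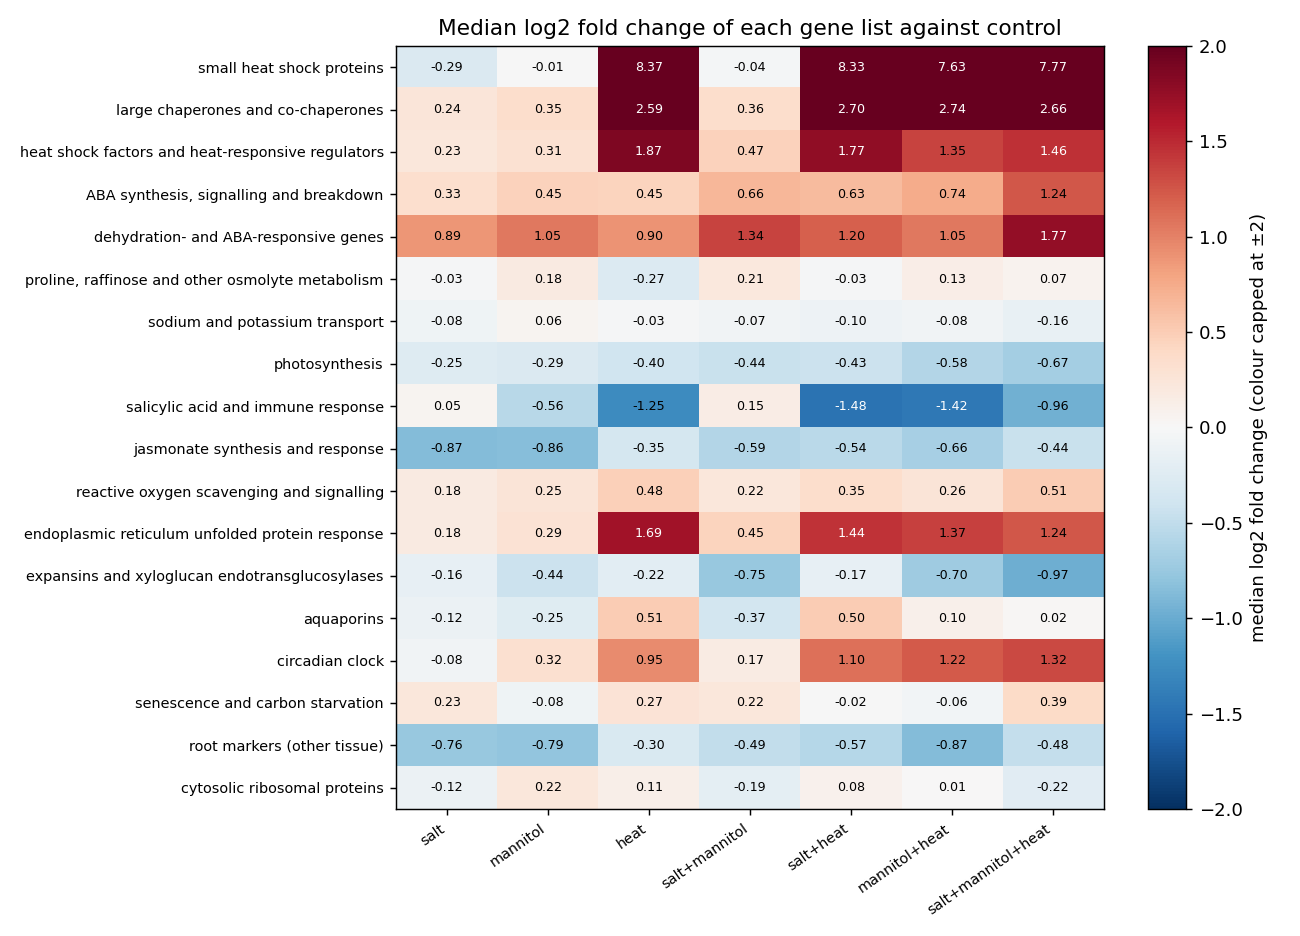
Median log2 fold change of each gene list in the 7 treatments against control.

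Salt plus mannitol raised LEA7 by log2 7.84 ± 1.36 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000398, TPM 60.7 ± 30.3 against 0.242 ± 0.110, n = 3 per group), LTP4 by 7.03 ± 0.89 (TPM 1033 ± 284 against 7.41 ± 3.99) and AT3G02480 by 6.48 ± 0.96. GSTF3 (5.93 ± 0.48), the late embryogenesis abundant gene AT3G17520 (5.89 ± 0.97) and RD29B (5.81 ± 0.89) followed. PCC1 fell by 3.19 ± 0.36, AT3G55646 (-3.22 ± 0.41), MSRB7 (-3.18 ± 0.66), the auxin-responsive AT4G34790 (-2.97 ± 0.44), AT1G22690 (-2.77 ± 0.36) and AT3G22235 (-2.72 ± 0.38).

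Of 27 dehydration- and ABA-responsive genes, 21 rose, 1 fell and 5 were not called (22 and 2 adjusted over the list alone). The camera value was adjusted p = 3.98e-13 (adjusted p = 0.311 with an estimated correlation). Of 21 ABA genes, 16 rose, 3 fell and 2 were not called, with the phosphatase genes HAI2 (2.35 ± 0.44) and HAI1 (2.24 ± 0.56) up and the receptor PYL4 down (-1.60 ± 0.21). Against all other genes, camera gave adjusted p = 3.22e-05 (adjusted p = 0.355 with an estimated correlation). In photosynthesis (39), 0 rose, 34 fell and 5 were not called (0 and 37 adjusted over the list alone), with RBCS3B (-1.03 ± 0.14), DRT112 (-0.76 ± 0.09) and PSAN (-0.74 ± 0.12). Camera ranked it at adjusted p = 5.20e-13 (adjusted p = 0.355 with an estimated correlation). The unfolded protein response list (15) rose: 13 rose, 0 fell and 2 were not called (14 and 0 adjusted over the list alone), with ERDJ3A (1.01 ± 0.19), BZIP60 (0.92 ± 0.13) and PDIL1-1 (0.77 ± 0.11). Its camera result was adjusted p = 8.63e-08 (adjusted p = 0.311 with an estimated correlation). Aquaporins (16) fell: 0 rose, 11 fell and 5 were not called (0 and 12 adjusted over the list alone), led by TIP2;1 (-1.78 ± 0.30), PIP1;5 (-1.56 ± 0.20), TIP1;2 (-1.41 ± 0.20) and PIP2;7 (-1.28 ± 0.15). The camera test gave adjusted p = 1.90e-05 (adjusted p = 0.341 with an estimated correlation). Cell wall genes (13) fell too: 0 rose, 6 fell and 7 were not called, with EXPA8 (-2.01 ± 0.42), XTH4 (-1.55 ± 0.27) and XTH9 (-1.37 ± 0.22). Tested by camera, it had adjusted p = 0.000549 (adjusted p = 0.402 with an estimated correlation). Cytosolic ribosomal proteins (223), with more rises than falls under mannitol, gave more falls than rises here, though most were not called in either. Here 7 rose, 54 fell and 162 were not called (7 and 49 adjusted over the list alone). The list stood at camera adjusted p = 1.99e-05 (adjusted p = 0.680 with an estimated correlation).

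The salicylic acid and immune list (24) was mixed: 8 rose, 5 fell and 11 were not called (9 and 5 adjusted over the list alone), with PR5 (2.76 ± 0.42, TPM 469 ± 9.85 against 68.5 ± 40.9) and the camalexin synthesis gene PAD3 (2.42 ± 0.48) up and WRKY54 down (-2.32 ± 0.19). Jasmonate genes (21) gave 1 rise and 12 falls, with THI2.1 (-2.49 ± 0.62), VSP1 (-2.44 ± 0.58) and JAZ7 (-1.85 ± 0.46). Camera returned adjusted p = 0.00132 (adjusted p = 0.475 with an estimated correlation). Osmolyte genes (17) gave 8 rises and 5 falls, with GOLS2 (1.83 ± 0.24) and P5CS1 (1.39 ± 0.20). Rises and falls were 7 and 2 for large chaperones (17), with HSP70 at 2.16 ± 0.28, 8 and 2 for heat shock factors (15), 4 and 2 for reactive oxygen (19), 3 and 0 for the clock (15), 4 and 1 for senescence (15), 0 and 1 for root markers (4) and 0 and 0 for small heat shock proteins (13). Sodium and potassium transport (17) gave 4 and 5, but 5 and 3 with library totals alone.

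In this comparison 6524 genes passed the test, 3083 higher and 3441 lower, and 1224 differed at least 2-fold. With TMM factors 47.3% of the calls were higher, and with library totals alone 69.7% of 7599 calls. Without control 1, AT3G02480 stood at log2 7.14 and VSP1 at -1.73. Without control 2, RD29B stood at log2 6.68. Without salt plus mannitol 3, MSRB7 stood at log2 -5.06.

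Salt plus heat resembled heat in its leading genes. AT4G19430 rose at least 342-fold and AT5G38650 at least 216-fold from no control counts. HSP21 rose by log2 9.98 ± 0.84 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.03e-08, TPM 219 ± 111 against 0.218 ± 0.205, n = 3 per group), with HSP22.0 (9.62 ± 0.75), AT1G71000 (9.32 ± 0.39) and HSP23.6 (9.14 ± 0.26) close behind, and APX2 had a count ratio of 571 (158 to 4719). PCC1 fell by 6.03 ± 0.43, PCR1 (-5.09 ± 0.75), MEE3 (-4.70 ± 0.39), ATCSLA15 (-4.60 ± 0.34), AIG1 (-4.51 ± 0.64) and LHY (-4.50 ± 0.22).

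Of 13 small heat shock proteins, 12 rose, 0 fell and 1 was not called (median 8.33, camera adjusted p = 3.32e-12, adjusted p = 0.0859 with an estimated correlation). Of 17 large chaperones, 16 rose, 0 fell and 1 was not called, led by HOP3 (7.86 ± 0.16), HSP70 (7.78 ± 0.33) and FKBP65 (7.25 ± 0.15). For this list camera gave adjusted p = 4.86e-15 (adjusted p = 0.0318 with an estimated correlation). Of 15 heat shock factors and regulators, 11 rose, 2 fell and 2 were not called, including HSFA2 (6.91 ± 0.21) and MBF1C (5.12 ± 0.16). Camera put it at adjusted p = 7.55e-05 (adjusted p = 0.260 with an estimated correlation). Dehydration- and ABA-responsive genes (27) rose: 18 rose, 0 fell and 9 were not called, with LTP4 (8.00 ± 0.92), LTP3 and RD29B among the rises. This list reached camera adjusted p = 0.00104 (adjusted p = 0.637 with an estimated correlation). The salicylic acid and immune list (24) fell: 0 rose, 20 fell and 4 were not called, with WRKY38 (-3.37 ± 0.33), PR1 (-2.56 ± 0.69) and WRKY54 (-2.47 ± 0.19). The camera value was adjusted p = 2.84e-06 (adjusted p = 0.341 with an estimated correlation). In photosynthesis (39), 1 rose, 28 fell and 10 were not called, with LHCB2.3 (-2.43 ± 0.14) and SBPASE (-1.16 ± 0.11). Against all other genes, camera gave adjusted p = 4.00e-05 (adjusted p = 0.619 with an estimated correlation). Aquaporins (16) gave 12 rises and 2 falls, led by PIP2;3 (3.19 ± 0.16) and TIP1;1 (1.75 ± 0.12). Camera ranked it at adjusted p = 0.00515 (adjusted p = 0.503 with an estimated correlation). The unfolded protein response (15) gave 13 rises and 1 fall. Camera put it at adjusted p = 7.86e-08 (adjusted p = 0.311 with an estimated correlation).

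Osmolyte genes (17) gave 5 rises and 7 falls, with ERD5 (-3.01 ± 0.30), GOLS1 (2.27 ± 0.13) and P5CR (2.13 ± 0.10). Senescence genes (15) gave 4 rises and 3 falls, led by the sugar transporter SWEET15 (5.31 ± 0.82, TPM 33.1 ± 16.3 against 0.815 ± 0.985) and ORE1 (1.87 ± 0.20), with a median of -0.02, a mean of 0.17 and a camera direction of up (camera adjusted p = 0.601). Rises and falls were 11 and 4 for ABA genes (21), 1 and 8 for jasmonate (21), 8 and 7 for reactive oxygen (19), 11 and 3 for the clock (15), 1 and 3 for cell wall genes (13), 4 and 6 for sodium and potassium transport (17), 75 and 41 for ribosomal proteins (223) and 0 and 2 for root markers (4).

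With salt plus heat, 12654 genes passed the test, 6340 higher and 6314 lower, and 3912 differed at least 2-fold. With TMM factors 50.1% of the calls were higher, and with library totals alone 57.9% of 12608 calls. Mitochondrial-encoded genes were higher for 60 of 61 (median 3.34). Without control 3, HSP21 stood at log2 10.96. APX2, at log2 8.825 in the full fit, stood at 11.48 without control 3. RD29B, at log2 4.197 in the full fit, stood at 5.065 without control 2. Without control 1, PCR1 stood at log2 -4.03, AIG1 at -3.37, PR1 at -1.54 and SWEET15 at 6.86. Without salt plus heat 3, PCR1 stood at log2 -5.91 and PR1 at -3.65.

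Mannitol plus heat raised AT5G38650 at least 193-fold and AT4G19430 at least 69.2-fold. HSP21 rose by log2 9.49 ± 0.85 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 4.06e-08, TPM 157 ± 74.4 against 0.218 ± 0.205, n = 3 per group), HSP22.0 by 9.45 ± 0.75 and HSP23.6 by 8.83 ± 0.26, and APX2 had a count ratio of 538 (149 to 4449.9). PCC1 fell by 6.60 ± 0.45. AT3G22235, an abundant gene annotated as a cysteine-rich stress tolerance protein, fell by 5.20 ± 0.43 (TPM 188 ± 128 against 6456 ± 1564), followed by AIG1 (-4.69 ± 0.65), PCR1 (-4.56 ± 0.70), LHY (-4.49 ± 0.22) and MEE3 (-4.38 ± 0.37).

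Of 13 small heat shock proteins, 12 rose, 0 fell and 1 was not called (median 7.63, camera adjusted p = 7.09e-12, adjusted p = 0.0859 with an estimated correlation). Of 17 large chaperones, 16 rose, 0 fell and 1 was not called, with HSP70 (7.55 ± 0.33), HOP3 (7.49 ± 0.16) and FKBP65 (6.94 ± 0.15). Its camera result was adjusted p = 6.35e-15 (adjusted p = 0.0318 with an estimated correlation). Of 15 heat shock factors and regulators, 11 rose, 2 fell and 2 were not called, with HSFA2 (6.47 ± 0.21) and MBF1C (4.88 ± 0.16). The camera test gave adjusted p = 8.76e-05 (adjusted p = 0.260 with an estimated correlation). Dehydration- and ABA-responsive genes (27) rose: 17 rose, 1 fell and 9 were not called, with LTP4 (8.62 ± 0.93), LTP3 (5.62 ± 0.52), RD29B (4.55 ± 0.92) and TSPO (4.08 ± 0.97). Tested by camera, it had adjusted p = 0.000857 (adjusted p = 0.637 with an estimated correlation). Of 21 ABA genes, 15 rose, 4 fell and 2 were not called, with HAI2 (2.68 ± 0.44), HAI1 (2.50 ± 0.56) and ABI1 (1.58 ± 0.13) at camera adjusted p = 0.0603. In photosynthesis (39), 0 rose, 33 fell and 6 were not called, with LHCB2.3 (-2.51 ± 0.14), RBCS1A (-1.39 ± 0.12) and LHCB1.3 (-1.16 ± 0.08). The list stood at camera adjusted p = 5.74e-08 (adjusted p = 0.475 with an estimated correlation). The salicylic acid and immune list (24) fell: 1 rose, 16 fell and 7 were not called, with PR1 (-3.33 ± 0.72), WRKY38 (-3.27 ± 0.33) and WRKY54 (-3.07 ± 0.20). Camera returned adjusted p = 1.90e-05 (adjusted p = 0.355 with an estimated correlation). Jasmonate genes (21) gave 1 rise and 12 falls, with TAT3 (-2.95 ± 0.72) and JAZ10 (-1.93 ± 0.35) at camera adjusted p = 0.0673.

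Osmolyte genes (17) gave 4 rises and 6 falls, but 7 and 6 with library totals alone, with GOLS2 up (2.04 ± 0.24) and ERD5 down (-3.06 ± 0.30). Their median was 0.13, their mean -0.09 and their camera direction up (camera adjusted p = 0.899). For senescence (15) the median was -0.06, the mean 0.38 and the camera direction up (camera adjusted p = 0.636), with 4 rises led by SWEET15 (5.78 ± 0.81) and 2 falls. Rises and falls were 13 and 1 for the unfolded protein response (15), 7 and 3 for aquaporins (16), with PIP2;3 at 2.66 ± 0.16, 1 and 8 for cell wall genes (13), with EXPA1 at -1.49 ± 0.32, 8 and 4 for reactive oxygen (19), 11 and 3 for the clock (15), 4 and 7 for sodium and potassium transport (17), 62 and 53 for ribosomal proteins (223) and 0 and 2 for root markers (4).

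With mannitol plus heat, 12950 genes passed the test, 6534 higher and 6416 lower, and 4106 differed at least 2-fold. With TMM factors 50.5% of the calls were higher, and with library totals alone 60.9% of 12816 calls. Mitochondrial-encoded genes were higher for 61 of 61 (median 4.06). Chloroplast-encoded genes were higher for 45 of 81, in a group where mannitol plus heat 2 alone held 0.626% of its counts in such genes. Without control 3, HSP21 stood at log2 10.49. APX2, at log2 8.75 in the full fit, stood at 11.42 without control 3. Without mannitol plus heat 2, HSP22.0 stood at log2 8.81. Without mannitol plus heat 3, PCC1 stood at log2 -7.42, AT3G22235 at -5.87, AIG1 at -5.47, PCR1 at -5.88 and EXPA1 at -2.10. Without control 1, AIG1 stood at log2 -3.56, PCR1 at -3.51, TSPO at 4.70, PR1 at -2.32, TAT3 at -1.86 and SWEET15 at 7.32. Without control 2, RD29B stood at log2 5.41.

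All 3 stresses at once raised LTP4 by log2 9.88 ± 0.97 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.27e-07, TPM 7341 ± 1453 against 7.41 ± 3.99, n = 3 per group) and HSP21 by 10.68 ± 0.84 (TPM 357 ± 113 against 0.218 ± 0.205). AT5G38650 rose at least 332-fold and AT4G19430 at least 131-fold. FTSH6, a chloroplast protease gene, rose by 9.43 ± 0.86 and HSP22.0 by 9.34 ± 0.75, and APX2 had a count ratio of 671 (185 to 5548). PCC1 fell by 7.31 ± 0.47 (TPM 21.4 ± 2.44 against 3139.6 ± 797), ATCSLA15 (-6.67 ± 0.43), MEE3 (-6.57 ± 0.49), the glutaredoxin gene AT3G21460 (-5.58 ± 0.72), PDF1.3 (-5.49 ± 1.53) and PORA (-5.45 ± 0.29).

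Of 27 dehydration- and ABA-responsive genes, 22 rose, 0 fell and 5 were not called (23 and 0 adjusted over the list alone), with LEA7 (7.28 ± 1.41), LTP3 (6.47 ± 0.54) and RD29B (5.79 ± 0.89) beside LTP4. This list reached camera adjusted p = 1.79e-06 (adjusted p = 0.475 with an estimated correlation). Of 21 ABA genes, 17 rose, 4 fell and 0 were not called, with HAI1 (3.29 ± 0.56), HAI2 (3.20 ± 0.44), NCED3 (2.00 ± 0.29) and CYP707A2 (1.95 ± 0.21). For this list camera gave adjusted p = 0.00357 (adjusted p = 0.503 with an estimated correlation). In photosynthesis (39), 0 rose, 36 fell and 3 were not called, with LHCB2.3 (-3.06 ± 0.14), RBCS1A (-1.67 ± 0.12) and LHCB1.3 (-1.31 ± 0.08). Camera put it at adjusted p = 8.75e-10 (adjusted p = 0.439 with an estimated correlation). Cell wall genes (13) fell: 1 rose, 11 fell and 1 was not called, with EXPA8 (-2.40 ± 0.44), EXPA1 (-2.30 ± 0.34) and XTH8 (-2.09 ± 0.26). This list reached camera adjusted p = 0.00541 (adjusted p = 0.475 with an estimated correlation). Of 13 small heat shock proteins, 12 rose, 0 fell and 1 was not called (median 7.77, camera adjusted p = 1.15e-11, adjusted p = 0.0859 with an estimated correlation). Of 17 large chaperones, 17 rose, 0 fell and 0 were not called, with HOP3 (7.46 ± 0.16), HSP70 (7.23 ± 0.33) and FKBP65 (6.77 ± 0.15). The camera value was adjusted p = 5.04e-14 (adjusted p = 0.0321 with an estimated correlation). Of 15 heat shock factors and regulators, 12 rose, 2 fell and 1 was not called, with HSFA2 (6.20 ± 0.21) and MBF1C (4.34 ± 0.16). Against all other genes, camera gave adjusted p = 0.000162 (adjusted p = 0.280 with an estimated correlation).

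Cytosolic ribosomal proteins (223) gave more falls than rises: 45 rose, 104 fell and 74 were not called, with AT3G11120 (-1.56 ± 0.09) and AT5G02440 (-1.65 ± 0.22) down. The camera value was adjusted p = 0.0186 (adjusted p = 0.808 with an estimated correlation). Senescence genes (15) gave 6 rises and 2 falls, with SWEET15 (6.53 ± 0.81) and NYC1 (1.41 ± 0.11). Osmolyte genes (17) gave 8 rises and 6 falls, with GOLS3 (-3.35 ± 0.22), ERD5 (-2.84 ± 0.29) and GOLS2 (1.92 ± 0.24); the median was 0.07, the mean -0.07 and the camera direction up (camera adjusted p = 0.712). Rises and falls were 3 and 15 for salicylic acid (24), 1 and 9 for jasmonate (21), 9 and 5 for reactive oxygen (19), 14 and 1 for the unfolded protein response (15), 6 and 6 for aquaporins (16), 11 and 3 for the clock (15), 4 and 8 for sodium and potassium transport (17) and 0 and 2 for root markers (4).

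With all 3 stresses, 13156 genes passed the test, 6613 higher and 6543 lower, and 4403 differed at least 2-fold. With TMM factors 50.3% of the calls were higher, and with library totals alone 63.5% of 13283 calls. Mitochondrial-encoded genes were higher for 59 of 61 (median 3.52). Without control 3, HSP21 stood at log2 11.67. APX2, at log2 8.98 in the full fit, stood at 11.66 without control 3. AT4G19430, at log2 9.89 in the full fit, stood at 8.98 without salt plus mannitol plus heat 3. Without control 2, FTSH6 stood at log2 10.62 and RD29B at 6.65. Without control 1, PDF1.3 stood at log2 -4.03 and SWEET15 at 8.07. Without salt plus mannitol plus heat 2, PORA stood at log2 -6.25.

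**Figure D3:**
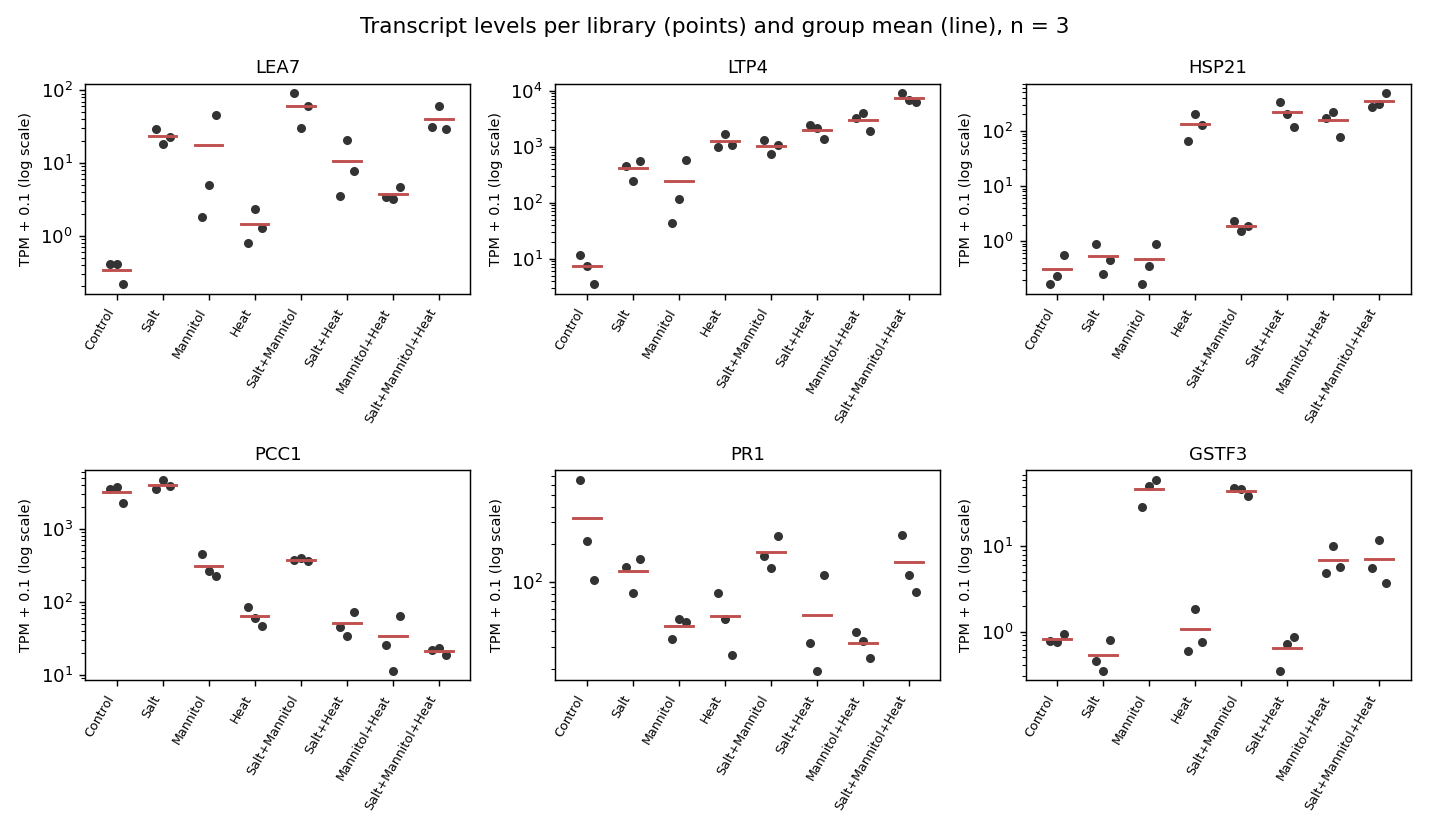
TPM of the leading genes in each library, grouped by treatment.

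Adding salt to heat changed few genes. NIA1, a nitrate reductase gene, fell by log2 1.93 ± 0.16 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.90e-07, n = 3 per group), as did the thionin AT1G66100 (-1.61 ± 0.25). HIPP22 rose by 2.15 ± 0.34 and AT3G53980 by 2.06 ± 0.33. FTSH6 rose by 2.66 ± 0.46, a call lost with 1 library left out (2.03 and adjusted p = 0.0576 without salt plus heat 1). The aquaporin TIP2;2 fell by 0.64 ± 0.11, 2 of 16 aquaporins falling in all. In this comparison 206 genes passed the test, 73 higher and 133 lower. The count fell to 45 without heat 2, 112 without heat 3, 46 without salt plus heat 1 and 41 without salt plus heat 2. With TMM factors 35.4% of the calls were higher, and with library totals alone 48.9% of 178 calls.

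Adding mannitol to heat raised the chitinase family gene AT2G43590 by log2 5.33 ± 0.53 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.00e-05, TPM 294 ± 31.0 against 7.30 ± 2.89, n = 3 per group), its neighbour AT2G43580 by 3.29 ± 0.57 and the defence gene PR5 by 3.35 ± 0.45. The ferritin genes FER1 (-2.92 ± 0.50, TPM 135 ± 27.4 against 1022 ± 605) and FER3 (-2.64 ± 0.40) fell, as did the heat-raised AT4G19430 (-2.64 ± 0.51) and AT1G56660 (-2.43 ± 0.48). Aquaporins (16) fell: 0 rose, 13 fell and 3 were not called (0 and 14 adjusted over the list alone), with PIP2;3 at -0.82 ± 0.15. In photosynthesis (39), 0 rose, 10 fell and 29 were not called (0 and 19 adjusted over the list alone), with LHCB4.3 (-1.36 ± 0.20) and DRT112 (-0.38 ± 0.09). Osmolyte genes GOLS2 (1.13 ± 0.23), P5CS1 (1.07 ± 0.20) and RS5 (0.65 ± 0.11) rose. HSP17.6II fell by 1.05 ± 0.22, 3 of 13 small heat shock proteins falling in all.

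In this comparison 2466 genes passed the test, 1201 higher and 1265 lower. It was 948 without heat 2 and 1496 without mannitol plus heat 1. With TMM factors 48.7% of the calls were higher, and with library totals alone 71.0% of 2819 calls. Without heat 2, FER1 stood at log2 -2.34, FER3 at -2.03 and AT1G56660 at -1.82.

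Adding mannitol to salt at 22 °C raised GSTF3 by log2 6.65 ± 0.53 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.23e-07, TPM 45.0 ± 4.78 against 0.431 ± 0.239, n = 3 per group), AT2G43590 by 5.32 ± 0.51, AT3G12910, of the NAC family, by 5.23 ± 0.39 and PXMT1 by 4.93 ± 0.51. AT1G06137 rose at least 9.92-fold from no counts with salt. The cell wall genes XTH25 (-5.07 ± 0.82) and XTH22 (-3.20 ± 0.56, TPM 7.80 ± 1.37 against 71.0 ± 9.64) fell, with the ethylene synthesis gene ACS11 (-4.66 ± 0.74) and PCC1 (-3.49 ± 0.37). Aquaporins (16) gave 2 rises and 7 falls, with TIP2;1 (-1.92 ± 0.31) and PIP1;5 (-1.62 ± 0.20). Of 21 jasmonate genes, 6 rose, 0 fell and 15 were not called (7 and 1 adjusted over the list alone), with the synthesis genes AOC1 (1.14 ± 0.22), AOC2 (0.94 ± 0.13) and AOS (0.80 ± 0.14). Of 15 clock genes, 6 rose, 1 fell and 8 were not called (7 and 1 adjusted over the list alone), with RVE1 (1.18 ± 0.16), PRR5 (0.99 ± 0.14) and LHY (0.81 ± 0.16).

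In this comparison 4245 genes passed the test, 2063 higher and 2182 lower. Leaving libraries out in turn gave 2696 without salt 2, 2797 without salt 3 and 2682 without salt plus mannitol 1. With TMM factors 48.6% of the calls were higher, and with library totals alone 49.5% of 4150 calls. Without salt 3, PXMT1 stood at log2 5.54.

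Adding mannitol to salt plus heat raised AT2G43590 by log2 4.60 ± 0.50 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.26e-05, TPM 348 ± 164 against 14.2 ± 4.80, n = 3 per group), HSFA6A by 3.69 ± 0.70 and GSTF3 by 3.64 ± 0.62, and AT1G06137 at least 10.2-fold. AT4G02850 fell by 2.62 ± 0.51 and AT4G34790 (-2.50 ± 0.42). Cytosolic ribosomal proteins (223) fell: 1 rose, 114 fell and 108 were not called (2 and 162 adjusted over the list alone), with AT1G23410 (-1.12 ± 0.25) and AT5G28060 (-0.54 ± 0.10). Aquaporins (16) fell: 0 rose, 11 fell and 5 were not called (0 and 12 adjusted over the list alone), with PIP1;5 (-1.32 ± 0.20) and TIP1;1 (-0.83 ± 0.12). Of 15 heat shock factors and regulators, 2 rose, 5 fell and 8 were not called (2 and 6 adjusted over the list alone), with HSFB2B (-0.85 ± 0.10) and MBF1C (-0.78 ± 0.13). The 3 ABA breakdown genes CYP707A1 (1.29 ± 0.21), CYP707A3 (1.16 ± 0.26) and CYP707A2 (1.02 ± 0.19) rose.

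In this comparison 3450 genes passed the test, 1399 higher and 2051 lower. Fits with 1 library less gave 2078 without salt plus heat 1, 2251 without salt plus heat 2, 1561 without salt plus mannitol plus heat 1 and 2046 without salt plus mannitol plus heat 2. With TMM factors 40.6% of the calls were higher, and with library totals alone 64.9% of 3574 calls. Without salt plus mannitol plus heat 2, GSTF3 stood at log2 3.04.

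For salt and mannitol at 22 °C, the combination was compared with the sum of the log2 effects of each stress, from 12 libraries in 4 groups (n = 3 each). Watering enters both single effects, so departures here cannot be told apart from a watering effect. AIG1 lay above the sum by log2 4.56 ± 0.76 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00288), as did AT1G73325 (3.94 ± 0.72) and AT2G30760 (3.32 ± 0.67), and AGP7 lay below (-2.80 ± 0.39). Large chaperones (17) gave 1 above and 6 below the sum (1 and 10 adjusted over the list alone), with HSP70 (-1.68 ± 0.37), FKBP65 (-1.13 ± 0.19) and HSP70-1 (-1.03 ± 0.15). Jasmonate genes (21) gave 8 above and 0 below the sum (15 and 0 adjusted over the list alone), with LOX2 (1.42 ± 0.28) and JAZ9 (1.37 ± 0.19), and the immune regulator SARD1 lay above (1.41 ± 0.24). Cytosolic ribosomal proteins (223) gave 0 above and 29 below the sum (2 and 68 adjusted over the list alone), with AT3G46210 at -0.98 ± 0.17. In all, 1323 genes departed from the sum, 569 above and 754 below. The leave-one-out counts that moved most were 556 without control 2, 691 without salt 2, 651 without salt 3, 730 without mannitol 2, 776 without salt plus mannitol 1 and 735 without salt plus mannitol 3. Departures above the sum made up 43.0%, and 19.5% of 1675 with library totals alone. Without control 1, AIG1 stood at log2 3.43. Without mannitol 2, AT1G73325 stood at log2 4.73. Without salt plus mannitol 3, AT1G73325 stood at log2 3.30.

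For salt and heat, LTP3 lay below the sum (log2 -3.51 ± 0.62, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0141, n = 3 in each of 4 groups), as did FKBP65 (-1.18 ± 0.18). JAZ9 (1.29 ± 0.19), the jasmonate regulator MYC2 (0.97 ± 0.14) and the clock gene PRR5 (1.04 ± 0.18) lay above. Jasmonate genes (21) gave 4 above and 0 below the sum (7 and 0 adjusted over the list alone), dehydration- and ABA-responsive genes (27) 1 above and 4 below the sum (1 and 5 adjusted over the list alone) and large chaperones (17) 0 above and 2 below the sum (0 and 3 adjusted over the list alone). In all, 281 genes departed from the sum, 172 above and 109 below. With 1 library less it came to 98 without control 2, 58 without control 3, 138 without salt 1, 75 without salt 2, 56 without salt 3, 581 without heat 1, 51 without heat 2, 123 without heat 3, 60 without salt plus heat 1 and 63 without salt plus heat 2. Departures above the sum made up 61.2%, and 30.6% of 278 with library totals alone.

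For mannitol and heat, AT2G30766 lay above the sum by log2 3.63 ± 0.83 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0134, n = 3 in each of 4 groups), with AT2G30760 (3.07 ± 0.66) and AT5G05250 (2.82 ± 0.50). The oxygenase gene AT5G59530 (-3.77 ± 0.56), AT1G26410 (-3.77 ± 0.46) and FER1 (-3.31 ± 0.68) lay below. Cytosolic ribosomal proteins (223) gave 0 above and 47 below the sum (0 and 112 adjusted over the list alone), heat shock factors and regulators (15) 0 above and 4 below the sum (0 and 5 adjusted over the list alone), with MBF1C (-0.99 ± 0.20) and HSFB2B (-0.82 ± 0.16), and large chaperones (17) 0 above and 5 below the sum (0 and 7 adjusted over the list alone), with HSP70 (-1.92 ± 0.37), HSP90.2 (-0.81 ± 0.14) and HSP60 (-0.67 ± 0.14). Reactive oxygen genes APX1 (-1.17 ± 0.26), FSD1 (-0.91 ± 0.14) and CAT1 (-0.62 ± 0.12) lay below, and WRKY54 (2.12 ± 0.30) and MYC2 (1.08 ± 0.14) above. In all, 1758 genes departed from the sum, 718 above and 1040 below. Counts with 1 library removed were 855 without control 2, 962 without control 3, 941 without mannitol 2, 1152 without mannitol 3, 881 without heat 2 and 1046 without mannitol plus heat 1. Departures above the sum made up 40.8%, and 32.6% of 1777 with library totals alone. Without mannitol 3, FER1 stood at log2 -2.46. Without heat 2, FER1 stood at log2 -2.71.

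For all 3 stresses against the sum of the single effects, LTP4 lay below (log2 -8.31 ± 1.72, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00785, n = 3 in each of 5 groups) and LTP3 (-5.60 ± 0.94), although each reached its highest level here. For LTP4 the summed effects, set on its control level, exceed the total of a whole library. A value below the sum was therefore bound to occur for LTP4 and shows no interaction. Watering enters the sum with salt and again with mannitol, so departures here cannot be told apart from a watering effect. AT1G73325 lay above the sum (4.95 ± 0.91), with WRKY54 (3.04 ± 0.37), SARD1 (2.03 ± 0.36) and JAZ9 (1.94 ± 0.27). Large chaperones (17) gave 0 above and 11 below the sum, with HSP70 (-4.29 ± 0.56), FKBP65 (-2.07 ± 0.27) and HOP3 (-1.59 ± 0.35), heat shock factors and regulators (15) 0 above and 5 below the sum (1 and 5 adjusted over the list alone), with HSFA2 (-2.62 ± 0.52), MBF1C (-2.29 ± 0.30) and HSFB2A (-1.93 ± 0.40), and ribosomal proteins (223) 0 above and 39 below the sum (1 and 79 adjusted over the list alone). In all, 1847 genes departed from the sum, 825 above and 1022 below. The same count was 620 without control 2, 777 without control 3 and 1192 without salt plus mannitol plus heat 1. Departures above the sum made up 44.7%, and 28.7% of 1980 with library totals alone. Without control 2, AT1G73325 stood at log2 4.29. Without mannitol 2, AT1G73325 stood at log2 5.74. Without control 1, LTP4 stood at log2 -9.17 and LTP3 at -6.36. Without control 3, LTP4 stood at log2 -7.65 and LTP3 at -4.94. Without mannitol 3, LTP4 stood at log2 -6.62 and LTP3 at -4.92.

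Salt and mannitol changed 964 genes in the same direction and 94 in opposite directions, where 257 in the same direction would follow from independent calls (correlation of log2 changes 0.458). RD29B and LTP4 belong to this overlap. Salt and heat shared 1392 with 272 opposite (685 if independent, correlation 0.408), and mannitol and heat 2587 with 733 opposite (1479 if independent, correlation 0.276), with PCC1 lower in both. Without a library the same-direction overlap of salt and mannitol was 613 without control 2, 441 without control 3 and 611 without salt 1, and that of salt and heat 865 without control 2, 643 without control 3, 874 without salt 1, 814 without salt 2 and 836 without salt 3. In 20 simulated sets with no treatment effect, sharing the 3 control libraries alone gave a mean correlation of 0.497 (0.462 to 0.519), a mean covariance of 0.0209 (0.0198 to 0.0220) and at most 1 gene called in the same direction in both. The observed correlations are no larger than these. Sharing controls sets the correlation of unchanged groups near this level by design, so it cannot measure the part of the controls. The observed covariances were 0.103, 0.165 and 0.146, above the simulated range. Part of the excess can come from the shared controls, which at 3 are too few to divide between comparisons.

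Genes without functional assignment made up 22.5% of the 17446 genes called in at least 1 of 7 treatments and 30.5% of the 2581 others, an odds ratio of 0.663 (0.605 to 0.727, Fisher exact p = 4.12e-18). Pooled over 5 strata of expression the ratio was 0.810 (Mantel-Haenszel estimate). Counting only genes with at least a 2-fold change, it was 1.08 (1.01 to 1.16, Fisher exact p = 0.0281), on the other side of 1. Among genes that rose with heat the ratio was 1.13 (1.06 to 1.22, Fisher exact adjusted p = 0.000519) and among those that fell 0.729. For genes that rose with salt it was 0.914 (Fisher exact adjusted p = 0.280).

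The most abundant transcripts across groups were LHCB1.3 (mean TPM 16469), MT1A (13769.7), RBCS1A (13560.4), LHB1B2 (11284), MT3 (10014), and the most abundant gene of unknown function was AT2G01021 (9563). Its mean rests on 4 libraries: salt 1 at TPM 16615, mannitol 2 at 14513, salt plus mannitol 2 at 19164 and mannitol plus heat 2 at 137226, against 2897 in the highest control. Among the next genes without functional assignment, AT3G22235 stood at 6456 ± 1564 in control and fell to 481 ± 76.0 with heat (log2 -3.76 ± 0.40), and AT1G51402 went from 4712 ± 411 to 5714 ± 475 with heat (log2 0.26 ± 0.10). AT5G42530 stood at 5462 ± 1662 in control and 6542 ± 69.8 with salt plus mannitol, where it was not called. AT1G55673 was highest in control (3499.5 ± 253) and fell to 2382 ± 115 with all 3 stresses (log2 -0.58 ± 0.10, n = 3 each).

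**Figure D4:**
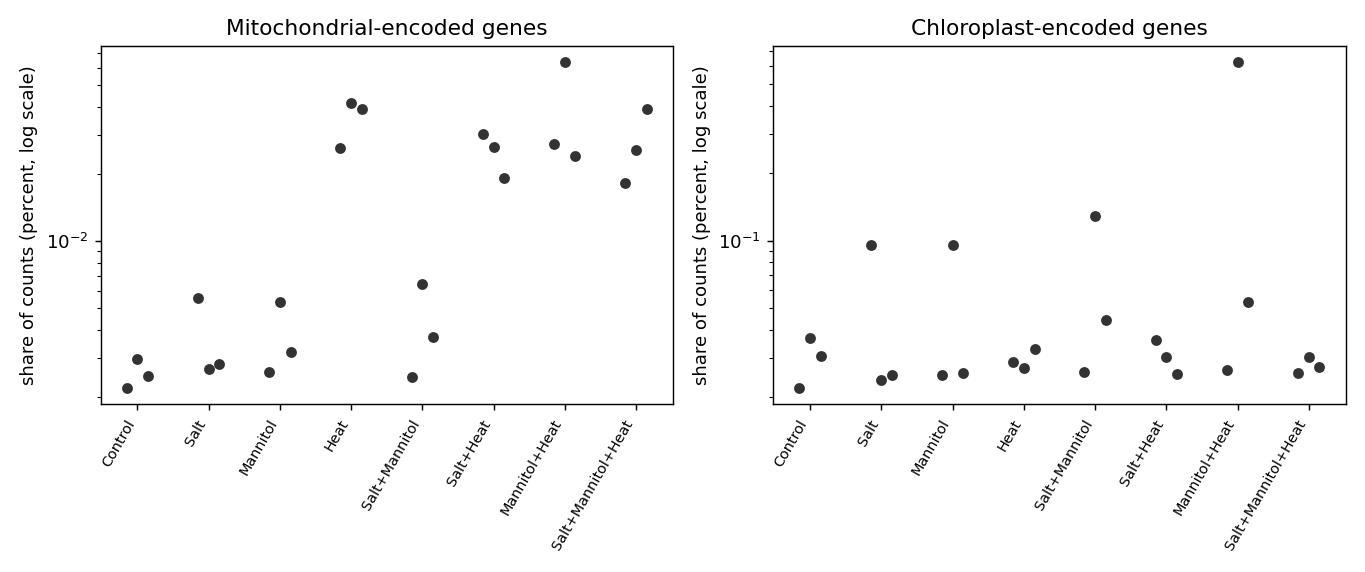
Share of counts in mitochondrial- and chloroplast-encoded genes in each of the 24 libraries.

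The authors' deposited sleuth results called 1667 genes for salt, 2642 for mannitol and 15850 for heat at the same limit on deposited q values. They included 63.7%, 54.0% and 96.2% of the calls made here. Correlations of the fold changes were 0.989 to 0.997 over the 7 treatments.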

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

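All tests of the mitochondrial pattern, and those of depth, a single library, organelle carry-over and treatment below, were chosen only after the result was seen; the splits of libraries, the held-out salt effects and the ribosomal repeat search were set before.

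The salt effect differed between 22 and 35 °C for 281 genes and the mannitol effect for 1758, each by the interaction test. Mannitol moved 93 genes in called opposite directions at the 2 temperatures. The lowest mitochondrial-encoded share of a heated library was 0.0183%, above every unheated library, and the chloroplast-encoded share of mannitol plus heat 2 was 0.626%.

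Mitochondrial-encoded genes were higher in all 12 heated libraries (0.0183 to 0.0636% of counts) than in the 12 others (0.00219 to 0.00642%), a ratio of medians of 9.33. Carry-over of RNA without poly(A) tails would raise chloroplast-encoded genes too, but their ratio of medians was 1.04. Reads moved away from nuclear copies of mitochondrial genes would lower those copies, which were higher at a ratio of 2.56. Reads shared between both sets could raise both together, so this ratio cannot judge sharing. Library depth did not separate the groups (8 of 12 heated totals lay inside the range of the others). The tests of carry-over and depth argue against these technical explanations, while shared reads remain open. Heat itself, more polyadenylated mitochondrial RNA and the other cabinet remain open and were not tested.

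AT2G01021 was far higher in 4 libraries of 4 groups. All 4 are also the 4 with the highest chloroplast-encoded share, which carry-over of ribosomal and chloroplast RNA would give. The gene's sequence lies within the ribosomal RNA repeat, 625 bases behind 2 of 2 annotated nuclear 5.8S genes. Only 2 of the 8 other libraries of these groups lay above the highest control, which argues against the stress treatment of the group. The abundance of this gene may therefore be ribosomal RNA left in some libraries.

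Salt changed 2193 genes at 22 °C and 206 at 35 °C, a difference larger than any single library accounts for. With 1 library left out the count at 35 °C was at most 281 and that at 22 °C at least 1043. Fits with fewer libraries tend to call fewer genes, so a rise at 35 °C was hard to obtain this way. Selection of genes on their own 22 °C values would leave a ratio near 1 when genes chosen on 2 replicates are measured on the third, but the 35 °C effect was 0.252, 0.267 and 0.287 of the held-out 22 °C effect. Library depth was alike, with a ratio of median totals of 1.04. The technical explanations tried thus leave the smaller effect of salt at 35 °C standing. An offset shared by all libraries of a group, such as the controls, cannot be seen by these tests. Whether the salt effect is smaller because heat came in the last 4 h of a 16 h salt treatment was not tested.

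Exchanging libraries between 2 groups of 3 makes 10 splits, so no share under 0.05 can occur. In all 11 comparisons of 2 groups only 1 split, the real one, gave as many called genes. Every other split mixes both groups, so a real difference widens the spread within the new groups. Low counts in these splits follow largely from that and do not measure chance. The highest other split gave 44 genes for salt plus heat against heat, 23 for mannitol, 4 for all 3 stresses against salt plus heat, 3 for mannitol plus heat against heat and 0 for the 7 others. In mannitol plus heat against heat, where the numbers may pair the samples, the same highest count bounds the splits that part as many pairs.

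For the additivity tests 25 splits were made. As many departures as in the real arrangement came in 2 splits for salt and mannitol (highest other 3210), 1 for salt and heat (highest other 2), 3 for mannitol and heat (highest other 9215) and 2 for all 3 stresses (highest other 3821), the real one included. Relabelling all libraries of such a contrast carries the effects of the single stresses into it, so these splits cannot judge the departures, and chance is neither excluded nor shown by them. Counts several times the real one can come from this known structure of the samples.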

How the results depend on the processing

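The use of deposited counts, limma, library totals alone, the 4 left-out libraries and other definitions of unknown function was chosen after the results were seen. 880 named gene values were refitted (875 of them with DESeq2, 874 with limma on TPM and as many in fits of only the groups compared), but not with the 4 libraries left out or the minimum fold. No sign changed where refitted. Calls were lost for 7 with DESeq2, 2 with RLE scaling, 42 with no filter on low genes, 8 with counts as deposited, 39 with limma, 41 with library totals alone, 28 with the replicate block and 163 in fits of only the groups compared, which hold fewer samples. With 1 library left out, the call was lost for 120 at their lowest value, 148 at their highest and 267 in any such fit. The fold moved by more than 1.5 times for 123 values, most often without control 1 (57 of 667) and mannitol 3 (19 of 206). The pseudocount alternative was not run because counts were available. Depths of 12.5 to 19.5 M reads limit calls among low genes.

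With the replicate block, the count for salt was 2112 and for mannitol plus heat against heat 2386, where alone all 3 same-number correlations were above 0.1 (0.117, 0.221 and 0.145), and where the block ended 1 named call, RAB18; no count moved by 1.5 times.

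A log2 fold change of at least 1, a stricter rule by construction, left 283 genes for salt, 814 for mannitol, 3672 for heat, 1224 for salt plus mannitol, 3912 for salt plus heat, 4106 for mannitol plus heat, 4403 for all 3 stresses, 247 for the departures for salt and mannitol, 57 for salt and heat, 391 for mannitol and heat, 764 for all 3 stresses, 42 for salt plus heat against heat, 365 for mannitol plus heat against heat, 840 for salt plus mannitol against salt, 622 for all 3 stresses against salt plus heat. Overlaps became 109, 138 and 251. The odds ratio for unknown function reversed to 1.08; the cause was not tested.

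With the 4 libraries left out, leaving fewer samples, counts were 1400 for salt, 673, 136 and 781 for the departures of salt and mannitol, salt and heat, and mannitol and heat, 1388 for mannitol plus heat against heat, and 593 and 871 for the overlaps of salt with mannitol and heat. DESeq2 gave 585 departures for salt and heat and 418 genes for salt plus heat against heat; the cause was not tested. Fits of only the groups compared gave 596 departures for mannitol and heat, 79 for salt plus heat against heat and 590 for mannitol plus heat against heat.

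Leaving out each library in turn gave 1043 to 1956 for salt, 556 to 1438 for the departures for salt and mannitol, 51 to 581 for salt and heat, 855 to 2424 for mannitol and heat, 620 to 2083 for all 3 stresses, 41 to 281 for salt plus heat against heat, 948 to 2879 for mannitol plus heat against heat, 2682 to 4125 for salt plus mannitol against salt, 1561 to 3080 for all 3 stresses against salt plus heat, and overlaps of 441 to 1013 and 643 to 1518 for salt with mannitol and heat.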

Other observations

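Mannitol moved some genes in opposite directions at 22 and 35 °C (edgeR, n = 3 per group). CTF2B, an oxidoreductase gene, rose at 22 and fell at 35 °C, in log2 (1.95 ± 0.16 and -0.66 ± 0.19), as did the small heat shock family gene AT1G59860 (1.78 ± 0.24 and -0.63 ± 0.13), the anion channel gene SLAH2 (0.66 ± 0.23 and -1.24 ± 0.31), the amino acid transporter gene LHT1 (0.69 ± 0.22 and -1.05 ± 0.26) and AT1G76800 (0.99 ± 0.16 and -0.64 ± 0.18). The immune regulator SIB1 (-0.67 ± 0.15 and 0.92 ± 0.17), the jasmonate regulator MYC2 (-0.63 ± 0.10 and 0.45 ± 0.10) and the purine transporter gene AZG1 (-0.79 ± 0.10 and 0.55 ± 0.11) fell at 22 and rose at 35 °C. Of 879 genes called for mannitol at each temperature, 786 kept their direction and 93 did not. The calls of the genes named here were not tried with libraries left out.

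AT5G38650, the proteasome maturation factor gene raised by heat, was silent or nearly so in control, salt and mannitol rosettes (highest TPM 0.000163, in salt 1). It stood at TPM 5.22, 3.49 and 4.49 in the 3 salt plus mannitol libraries at 22 °C, and at 14.6, 38.1 and 20.8 with heat. Values as low as that of salt 1 lie far below a single read and arise where reads are divided between transcripts. Reads shared with another transcript can therefore enter these levels, and this was not tested.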
